A study of Sus scrofa with 8 samples.

How the data were processed

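RNA of the longissimus dorsi was measured in 4 control and 4 melatonin libraries. Each library was taken to be a separate piglet, as the labels give only group and replicate number. Libraries were made from poly(A) RNA with dUTP marking of the second strand, per the labels' protocols. The deposited gene table holds, per the file headers, a count and an FPKM value (fragments scaled by transcript length and library size) for each of 23235 Ensembl genes in each library. The deposited counts are whole numbers and were not normalised. The deposited FPKM values scale the same counts by gene length and library: in 1813 genes with large counts the ratio of count to FPKM deviated by at most 0.112% from a gene constant times a library constant. FastQC, StringTie, DESeq2 and the Sscrofa11.1 build are named in the submitters' processing notes, without a role or version. The aligner and the annotation release are not given in the sources used here. The table covers chromosomes 1 to 18, X and Y, so the share of mitochondrially encoded genes was not computed. All columns of values were mapped to a library, with 0 left over. A total of 127 gene symbols were added from a table of gene names and 107 from NCBI gene numbers in the descriptions, and 8371 genes are named by an Ensembl ID only.

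Total counts ran from 53471667 to 60629098. No pair of libraries was a duplicate: the most similar pair still differed with a chi-square per degree of freedom of 75.7. Genes were kept at a mean FPKM of at least 1 over the 8 libraries, which left 9821. Counts were tested in edgeR 4.0.16 (R 4.3.3) with TMM scaling and the quasi-likelihood F test in its legacy form, melatonin against control with no covariate, and Benjamini-Hochberg adjustment with a threshold of 0.05. The common biological coefficient of variation was 28.0%. TMM factors were 1.02, 0.851, 1.01 and 1.02 in controls and 1.18, 0.923, 1.19 and 0.866 after melatonin, and no scaling used moved the median of all genes by over 0.1 on the log2 scale. The standard error of a log2 fold change is its size divided by the root of F.

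Before the data were examined, the tests, the alternatives, the 50 gene lists and the rule for naming genes had been fixed. The fixed design used limma on log2(FPKM + 1), and gave way to the quasi-likelihood test if counts were present, as they were. The limma fit is therefore an alternative for genes. Lists and terms were tested on log2(FPKM + 1) with camera in limma 3.58.1, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the 44 lists that had at least 4 genes past the filter. Printed medians of lists come from the edgeR fold changes. On the log2(FPKM + 1) values that camera tested, medians differed. They were nearer to 0 for respiratory complex I (-0.25 against -0.37) and mitochondrial ribosomal proteins (-0.07 against -0.17). The slow fibre list lay further from 0 (-0.72 against -0.58). Lists that pass are called at an adjusted p under 0.05. The fry test was run beside camera: its directional p asks whether the genes of a list move one way on balance, its mixed p whether they change in either direction, and neither compares the list with other genes. By the directional p 0 lists passed (smallest adjusted p = 0.932). GO and KEGG terms deposited in the table with 15 to 300 filtered genes were tested in the same way. Myosin heavy chain shares and library makeup were compared with two-sided exact permutation tests over all 70 assignments of the libraries, in Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and plots were drawn with Matplotlib 3.10.9.

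Genes are named by 3 parts of the rule. The first takes up to 12 genes per direction past the adjusted threshold, with places left over filled by the smallest unadjusted p among genes with a symbol and a fold of at least 1.5. None passed in edgeR, so all 24 places were filled in this way and none of those genes is past the threshold in that test. DESeq2 called most of them: all 12 in the upward direction, and each in the downward direction except LIMD1 and TMEM182. The second takes from each list described up to 4 members past the threshold, or else the 2 with the smallest unadjusted p. The third is a fixed set of muscle, clock, fat and antioxidant genes. Of the 83 genes so named, 16 overlap another gene of the table, 4 of them on the same strand. Below, overlaps are printed only for CHRNE and MYH7B. Others include PPARGC1B (mean 1.64 FPKM) with ssc-mir-378-1 (11.0) on the same strand. On the opposite strand NR1D1 (5.94) overlaps THRA (10.8), and TRPV3 (1.83) overlaps ASPA (0.68).

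The count test was tested on simulated counts for the 9821 genes at the means and library sizes of these samples. It recovered 2 of 50 genes changed by 1.5-fold (4%), 21 of 50 at 2-fold (42%), 48 of 50 at 4-fold (96%) and 50 of 50 at 8-fold (100%), with 4 false calls. Each gene was drawn independently, so spread shared between genes was left out. All changes were planted in the same run, which eases the adjusted threshold. The recovered shares therefore need not hold for the real samples. Alternatives were another pseudocount (0.1), no filter, a filter at a mean FPKM of 5, median-of-ratios and quantile scaling, other variance models, library weights, the replicate number as a block, each library left out in turn, DESeq2 1.42.0, an estimated correlation, fry and ranked camera. Chosen after seeing the data were the bias-adjusted quasi-likelihood test, camera on TMM log2 CPM, and leaving out melatonin replicates 1 and 3 together.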

Results

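Poly(A) RNA from the longissimus dorsi, the long back muscle, of Duroc x Landrace x Yorkshire piglets was sequenced in 8 libraries. Each was taken to be a separate piglet. Weaned animals aged 28 days had been randomised, 6 per group, to saline or to melatonin, the pineal hormone that signals darkness, at 5 mg per kg body weight. Both were given by gavage each day for 23 days after 5 days of adaptation. The 4 control and 4 melatonin libraries were compared. Total counts were 53690332, 57387202, 53471667 and 58930078 in control replicates 1 to 4 and 53891623, 59593451, 55225173 and 60629098 in melatonin replicates 1 to 4. The replicate labels give only numbers, so the p-values of genes and of exact tests below measure the spread between these samples. Camera p-values of lists and terms at the preset correlation of 0.01 do not, since they take genes as nearly independent. For complex I the estimated correlation was 0.67. Values are FPKM as mean ± SD (n = 4 per group), fold changes are log2 melatonin over control ± SE from edgeR, and positions refer to Sscrofa11.1.

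The comparison asks what 23 days of oral melatonin does to the muscle transcriptome. As a group, nuclear genes of the respiratory chain were lower after melatonin: all 33 genes of complex I, the entry point for electrons from NADH, lay below control, with a median log2 fold change of -0.37 (camera in limma, adjusted p = 8.91e-13). The muscle atrophy programme, the ligases and regulators that drive protein loss in fasting and disuse, was higher in 16 of 20 genes, with a median of 0.52 (adjusted p = 0.000992). Genes of the extracellular matrix were higher in 24 of 28, with a median of 0.80 (adjusted p = 0.000444), and this rested on melatonin replicates 1 and 3. Each of these list calls used a preset correlation between genes and was lost with an estimated one (adjusted p = 0.744 with an estimated correlation). No individual gene passed the adjusted test: edgeR's quasi-likelihood test called 0 of 9821 genes (smallest adjusted p = 0.440), limma on FPKM called 0 and DESeq2 called 65.

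At an unadjusted p under 0.05, edgeR gave 1032 genes, and 211 of them differed by at least 2-fold, 176 higher and 35 lower. Leaving out melatonin replicate 4 raised the called genes from 0 to 15 and the 211 to 412, and leaving out melatonin replicate 3 brought the 211 to 140. Without melatonin replicates 1 and 3 together, that count was 95, 49 higher and 46 lower. Among the genes with the smallest p in the upward direction, RASGEF1B, an exchange factor for Ras-family GTPases (ENSSSCG00000029507, chromosome 8, 136568711 to 136593702), measured 0.735 ± 0.267 FPKM in controls and 4.19 ± 1.94 after melatonin, a log2 fold change of 2.41 ± 0.40 (edgeR adjusted p = 0.440, DESeq2 adjusted p = 5.37e-06). TRPV3, a heat-sensitive cation channel (ENSSSCG00000017862, chromosome 12, 49635927 to 49671613), measured 0.547 ± 0.279 and 3.11 ± 1.72 FPKM (2.45 ± 0.47). MYLIP, a ubiquitin ligase that degrades the LDL receptor (ENSSSCG00000001063, chromosome 7, 12117240 to 12137925), measured 1.85 ± 0.303 and 4.52 ± 1.84 FPKM (1.16 ± 0.24). MYOC, which encodes the secreted glycoprotein myocilin (ENSSSCG00000035066, chromosome 9, 114087378 to 114098745), measured 7.57 ± 1.39 and 52.2 ± 44.3 FPKM (2.56 ± 0.56), with 91.7 and 89.2 FPKM in melatonin replicates 1 and 3 and 16.8 and 10.95 in replicates 2 and 4. HIST1H2BD, a histone gene from a family of near-identical copies among which reads can be shared, had a log2 fold change of 1.28 ± 0.26. The other 7 genes named by the same rule, CREB3L2, SYNE3, PCSK6, ZNF462, COL22A1, SLC35A2 and DENND4A, had values from 0.62 to 5.28. COL22A1, a collagen of muscle-tendon junctions, gave the highest of these. All 12 missed the adjusted threshold in edgeR, while DESeq2 called all 12. In FPKM the groups overlapped for COL22A1, MYLIP, SYNE3 and DENND4A. Each of the 12 except RASGEF1B, TRPV3 and HIST1H2BD had its highest FPKM values in melatonin replicates 1 and 3.

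Among genes lower after melatonin, CHRNE had the smallest p. It encodes the adult-type subunit of the acetylcholine receptor at the nerve-muscle synapse (ENSSSCG00000017909, chromosome 12, 52011250 to 52016299) and measured 5.27 ± 1.37 FPKM in controls and 2.18 ± 0.352 after melatonin, a log2 fold change of -1.30 ± 0.25 (edgeR adjusted p = 0.440, DESeq2 adjusted p = 0.00251). On the opposite strand it overlaps MINK1, a kinase gene, at a mean of 4.78 FPKM, and no source states whether strand was used in counting. ATPAF2, an assembly factor of the mitochondrial ATP synthase (ENSSSCG00000028712, chromosome 12, 60617649 to 60633271), measured 13.3 ± 3.25 and 6.96 ± 0.634 FPKM, with an SE of 0.23 on the log2 fold change. NMNAT2, an enzyme of NAD synthesis (ENSSSCG00000015557, chromosome 9, 124498109 to 124696194), measured 2.45 ± 0.475 and 1.30 ± 0.201 FPKM (-0.98 ± 0.19). DUSP1, a phosphatase that switches off stress-activated kinases (ENSSSCG00000016991, chromosome 16, 51458020 to 51461086), measured 23.5 ± 10.1 and 9.82 ± 3.27 FPKM (-1.41 ± 0.34). TMEM182, a muscle membrane protein gene, measured 20.4 ± 2.15 and 14.1 ± 1.05 FPKM (-0.59 ± 0.15). The coiled-coil gene CCDC9B measured 45.7 ± 4.07 and 29.7 ± 2.19 FPKM (-0.68 ± 0.17). CIB2, NLRX1, SLC2A11, LIMD1 and H2AC18, the last from a family of near-identical histone copies, lay between -1.18 and -0.69. The microRNA gene ssc-mir-10390 (chromosome 9, 4700784 to 4700878) had a log2 fold change of -5.10 ± 1.20, which came from control replicates 2 and 4 at 1984 and 2105 FPKM, against 56.1 and 57.7 in the other controls and 29.2 to 39.6 after melatonin. In FPKM the groups overlapped for DUSP1, CIB2, SLC2A11, LIMD1 and H2AC18, and 12 of 12 lower genes missed the adjusted threshold in edgeR. DESeq2 called each of these 12 except LIMD1 and TMEM182.

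**Figure D1:**
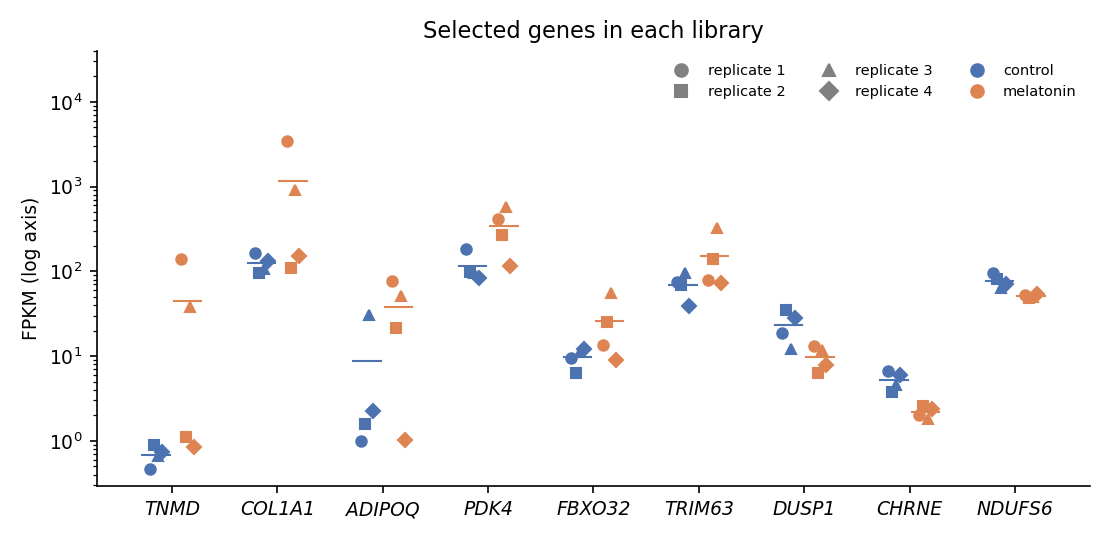
FPKM on a log axis for 9 genes in each of the 8 libraries, with colour for group, marker shape for replicate number and lines at the group means. CHRNE and NDUFS6 have groups that do not overlap, while TNMD and COL1A1 are high in melatonin replicates 1 and 3 alone.

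Energy metabolism gave the lists with the smallest adjusted p. Complex I had 11 of 33 genes lower at an unadjusted p under 0.05 and none higher. NDUFS6, an accessory subunit (ENSSSCG00000017114, chromosome 16, 78993913 to 79000006), measured 77.5 ± 13.8 FPKM in controls and 50.9 ± 2.58 after melatonin (-0.68 ± 0.19), and NDUFB8 measured 46.6 and 35.5 FPKM (-0.47). Complexes II to V were lower in 40 of 42 genes, with a median of -0.40 (limma camera adjusted p = 7.49e-12), among them COX5B at 84.6 ± 23.2 and 62.7 ± 6.93 FPKM and the muscle isoform COX6A2 at 92.9 and 72.5. TCA cycle enzymes were lower in 21 of 21, with a median of -0.30 (limma camera adjusted p = 4.54e-07), including IDH2 at 190 and 156 FPKM and SDHC at 24.3 and 18.4. Mitochondrial ribosomal proteins were lower in 56 of 64, with a median of -0.17 (limma camera adjusted p = 6.70e-05), led by MRPL37 (-0.85) and MRPL24 (-0.52). These 4 calls were lost with an estimated correlation (adjusted p = 0.744 with an estimated correlation). They held when any of the 8 libraries was left out, and no member passed when adjusted over the list alone or over all genes. Mean complex I levels overlapped between groups: control replicate 4 lay at -0.41 against the control mean, between melatonin replicates 1 and 3 at -0.56 and -0.43 and replicates 2 and 4 at -0.22 and -0.21. Without melatonin replicates 1 and 3, complex I (median -0.25) and complexes II to V (median -0.27) kept their calls, each at an adjusted p of 7.59e-05, as did mitochondrial ribosomal proteins (adjusted p = 0.0017), while the TCA list lost its call (adjusted p = 0.278).

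Regulators of mitochondrial content followed the same direction without passing as a list. PPARGC1A, the coactivator that drives mitochondrial biogenesis, measured 1.65 ± 0.227 FPKM in controls and 1.15 ± 0.422 after melatonin (-0.64 ± 0.25, edgeR adjusted p = 0.453), and its relative PPARGC1B measured 2.14 ± 0.419 and 1.14 ± 0.409 (-0.96 ± 0.33). The biogenesis and dynamics list of 20 genes had a median of -0.08 (limma camera adjusted p = 0.0995). Glycolysis and glycogen genes were lower in 22 of 24, with a median of -0.12 (limma camera adjusted p = 0.00189, and adjusted p = 0.744 with an estimated correlation). HK2, the inducible hexokinase, had a log2 fold change of -0.94, while PFKFB3, which makes an activator of glycolysis, had the opposite sign at 6.04 and 26.0 FPKM (2.03). The glycolysis call was lost without control replicate 2, melatonin replicate 1 or melatonin replicate 3, with adjusted p values up to 0.879. Without melatonin replicates 1 and 3 together it reversed to a median of 0.23 (adjusted p = 0.00099).

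Muscle fibre genes were described by type. The slow fibre contractile list was lower in 15 of 15 genes, with a median of -0.58 (limma camera adjusted p = 0.000180, and adjusted p = 0.744 with an estimated correlation), including the slow-tonic myosin MYH7B (-1.17 ± 0.45) and the calcium store protein CASQ2 (-1.02). The call was lost without melatonin replicate 2 (adjusted p = 0.125), whose list mean was -2.79 against -0.33 to 0.13 in the other melatonin libraries. On the opposite strand MYH7B, at a mean of 7.64 FPKM, overlaps TRPC4AP at 31.0 FPKM, and strand use in counting is not stated. The fast fibre contractile list was lower in 13 of 17 genes, with a median of -0.09, and did not pass (adjusted p = 0.306). It passed as lower without melatonin replicate 2 (adjusted p = 0.00995) or 4 (adjusted p = 0.0357), and as higher, with a median of 0.23, without melatonin replicates 1 and 3 (adjusted p = 0.000144). MYOD1, a master regulator of myogenesis, measured 4.34 ± 0.968 FPKM in controls and 1.97 ± 1.08 after melatonin (-1.18 ± 0.39), while its relative MYF5 measured 0.862 and 1.94 (1.02). The myogenesis list did not pass (17 genes, median -0.17, adjusted p = 0.174) except without melatonin replicate 4 (adjusted p = 0.0267).

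Myosin heavy chain makeup, a standard readout of fibre type, was not shown to differ between the groups beyond the spread between libraries. The slow isoform MYH7 took 8.55 ± 5.34% of the summed FPKM of the 4 adult isoforms in controls and 6.25 ± 4.25% after melatonin (SD, n = 4, two-sided exact permutation p = 0.543). MYH2, of oxidative fast fibres, took 6.97 ± 3.89% and 10.7 ± 6.06% (exact permutation p = 0.371). MYH1 took 35.7 ± 9.72% and 47.0 ± 16.2% (exact permutation p = 0.286), and MYH4, of the most glycolytic fibres, 48.8 ± 16.3% and 36.1 ± 21.4% (exact permutation p = 0.400). The adjusted p over these 4 isoforms was 0.533 for the fast isoforms and 0.543 for MYH7. MYH4 ranged from 33.2 to 69.7% in controls and from 13.7 to 63.4% after melatonin. These genes are close copies, so reads can be shared among them.

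**Figure D2:**
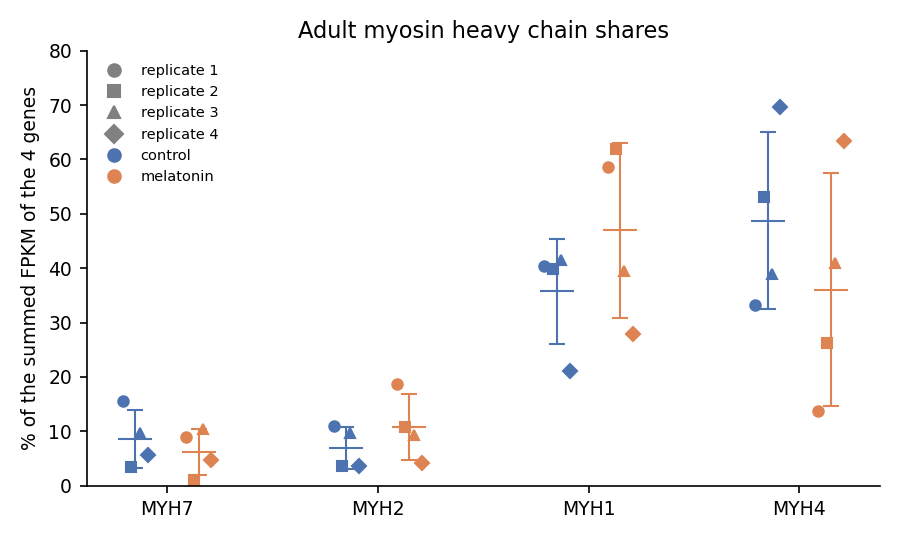
Percent of the summed FPKM of MYH7, MYH2, MYH1 and MYH4 in each library, as points by group with the mean ± SD (n = 4). The groups overlap for every isoform, and MYH4 spans 13.7 to 63.4% after melatonin.

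The atrophy programme held its call without any of the 8 libraries (highest adjusted p = 0.0166) and without melatonin replicates 1 and 3 together (median 0.35). It lost its call with an estimated correlation (adjusted p = 0.744 with an estimated correlation) and by fry (adjusted p = 0.932). In edgeR, 6 of its 20 genes passed when adjusted over the list alone, and 0 when adjusted over all genes. The higher ones were PDK4, which blocks pyruvate entry into the mitochondrion (115 ± 46.2 and 343 ± 197 FPKM, 1.41 ± 0.39), the transcription factor FOXO3 (5.34 and 13.8 FPKM), the stress sensor SESN1 (19.2 and 50.2 FPKM), CEBPD (2.85 and 12.3 FPKM) and the ligase FBXO30 (2.20 and 5.00 FPKM). TRIM54, a ligase of the sarcomere, was lower (35.4 ± 5.02 and 22.9 ± 4.84 FPKM, -0.70 ± 0.19). FOXO3, SESN1, CEBPD and FBXO30 were chosen after their values were seen. Of these 6 genes, DESeq2 called PDK4 and CEBPD over all genes (adjusted p = 0.0323 and 0.0476). The ubiquitin ligases that mark muscle wasting differed among the treated animals: FBXO32 measured 9.87 ± 2.57 FPKM in controls and 25.8 ± 21.0 after melatonin (1.26 ± 0.45), and TRIM63 measured 69.7 ± 23.8 and 154 ± 116 (1.00 ± 0.44), with edgeR adjusted p values of 0.446 and 0.473. Melatonin replicate 3 was highest for both, at 55.6 and 322 FPKM, followed by replicate 2 at 25.4 and 142. Replicate 1, at 13.5 and 78.6 FPKM, and replicate 4, at 8.91 and 72.1, lay at or near the controls, which reached 12.3 and 96.7. The list mean was 0.27, 0.72, 1.01 and 0.07 in melatonin replicates 1 to 4, against -0.11 to 0.08 in controls.

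Glucocorticoid targets, a set that shares 4 genes with the atrophy programme, were higher in 11 of 14, with a median of 0.35 (limma camera adjusted p = 0.0281, and adjusted p = 0.744 with an estimated correlation). In edgeR adjusted over the list alone, 4 passed, PDK4, CEBPD and the zinc-finger repressor ZBTB16 (7.72 and 19.9 FPKM) higher and DUSP1 lower. Adjusted over all genes, 0 passed in edgeR, while DESeq2 called PDK4, CEBPD and DUSP1 (adjusted p = 0.0323, 0.0476 and 0.0185). ZBTB16 was chosen after its values were seen. Proteasome subunits, which degrade tagged proteins, were lower in 37 of 42, with a median of -0.20 (limma camera adjusted p = 0.000444, and adjusted p = 0.744 with an estimated correlation), among them PSMB7 at 58.3 and 45.5 FPKM and PSMB4 (-0.34). Both calls were lost without control replicate 4 or melatonin replicate 1, with highest adjusted p values of 0.246 and 0.242. Genes of endoplasmic reticulum stress were higher in 17 of 21, with a median of 0.19 (limma camera adjusted p = 0.0354, and adjusted p = 0.744 with an estimated correlation), including DNAJC3 (0.65) and the stress sensor ATF6 (0.35). That call was lost without control replicate 1, 3 or 4 or melatonin replicate 1 or 3 (adjusted p up to 0.180). The autophagy list of 28 genes did not pass (adjusted p = 0.705) and had a median of -0.01 but a mean of 0.05 and an upward test, although GABARAPL1, a protein of the autophagosome membrane, measured 9.68 and 32.9 FPKM (1.60), with 67.5 in melatonin replicate 3 and 28.5, 26.7 and 8.95 in replicates 1, 2 and 4, and the mitophagy receptor BNIP3L 4.98 and 8.42 (0.65).

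Connective tissue genes separated 2 of the melatonin libraries from the other 6. The extracellular matrix list mean was 2.19 and 1.03 in melatonin replicates 1 and 3, against -0.20 and 0.05 in replicates 2 and 4 and -0.22 to 0.37 in controls. COL1A1, the main fibrillar collagen (ENSSSCG00000036135, chromosome 12, 26380305 to 26397004), measured 125 ± 30.8 FPKM in controls and 1158 ± 1577 after melatonin, with 3457 and 913 FPKM in replicates 1 and 3 and 110 and 151 in replicates 2 and 4. Tenomodulin, TNMD, a gene of tendon cells (ENSSSCG00000012480, chromosome X, 82269239 to 82292246), measured 139 and 37.7 FPKM in replicates 1 and 3, 1.12 and 0.85 in replicates 2 and 4, and 0.690 ± 0.182 in controls. In edgeR adjusted over the list alone, 5 matrix genes passed, COL12A1 (0.835 and 16.1 FPKM), TNC, THBS1, COL1A1 and COL1A2. Adjusted over all genes, 0 passed in edgeR, while DESeq2 called COL12A1 (adjusted p = 0.0494). TNMD, THBS1, COL1A1 and COL1A2 were chosen after their values were seen. The matrix call was lost without melatonin replicate 1 (adjusted p = 0.0971), and without replicates 1 and 3 the list reversed to a median of -0.09 (adjusted p = 0.569).

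Markers of cells that lie between the fibres were also called as higher with all 8 libraries, but not once melatonin replicates 1 and 3 were left out. Fibroblast and adipogenic progenitor markers were higher in 13 of 16, with a median of 0.56 (limma camera adjusted p = 0.0264). PI16, a marker of universal fibroblasts (ENSSSCG00000001570, chromosome 7, 32600770 to 32614924), measured 7.23 ± 2.14 and 17.2 ± 7.45 FPKM (1.12 ± 0.27) and was the 1 gene that passed when adjusted over the list alone, and the receptor PDGFRA had a log2 fold change of 0.80. Macrophage markers were higher in 10 of 11, with a median of 0.45 (limma camera adjusted p = 0.0256), including LYVE1 (0.415 and 2.10 FPKM) and the scavenger receptor CD163 (1.21). Adipocyte markers were higher in 11 of 14, with a median of 0.90 (limma camera adjusted p = 0.0446), among them PPARG (0.97). All 3 calls were lost with an estimated correlation (adjusted p = 0.744 with an estimated correlation). The fat hormone gene ADIPOQ measured 8.80 ± 14.4 FPKM in controls and 37.7 ± 33.5 after melatonin (1.92 ± 1.23), and the fatty acid binding protein FABP4 measured 41.0 ± 26.9 and 70.8 ± 52.8 (0.62 ± 0.58, with the opposite sign without melatonin replicates 1 and 3). Fat markers varied within the groups: the adipocyte list mean was 2.03 in control replicate 3 and -0.77 to -0.59 in the other controls, and -1.05 in melatonin replicate 4 against 1.41 to 2.43 in the other treated libraries. The fibroblast call was lost without control replicate 2, control replicate 3 or melatonin replicate 1 (adjusted p up to 0.199). The macrophage call was lost without control replicate 3 or melatonin replicate 1, 2 or 3 (adjusted p up to 0.167). The macrophage list mean was 0.96, 0.76, 1.11 and -0.52 in melatonin replicates 1 to 4, against -0.61 to 0.44 in controls. The adipocyte call was lost without control replicate 1, 2 or 4 or melatonin replicate 1, 2 or 3 (adjusted p up to 0.242). Without melatonin replicates 1 and 3 together, the medians were 0.02 for fibroblast markers (adjusted p = 0.531), 0.08 for macrophage markers (adjusted p = 0.504) and -0.01 for adipocyte markers (adjusted p = 0.504).

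**Figure D3:**
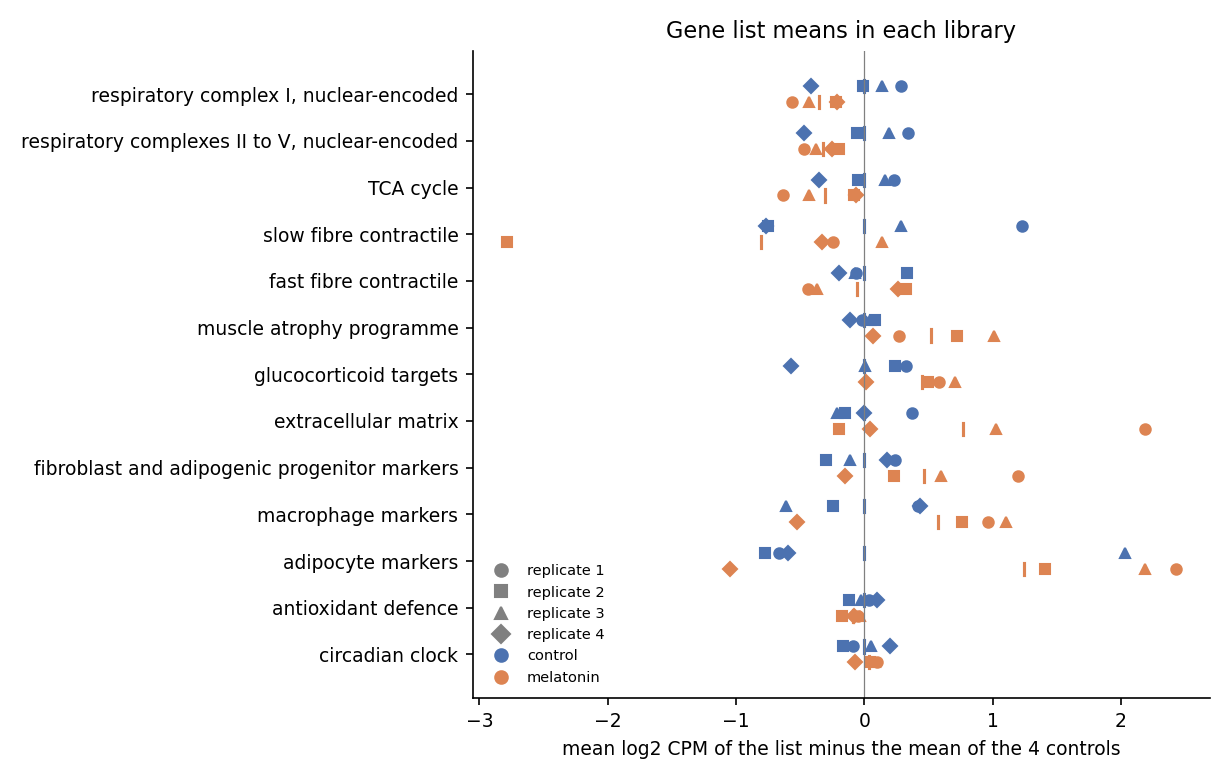
Mean log2 CPM of 13 gene lists in each library, relative to the control mean, with colour for group, marker shape for replicate number and ticks at the group means. Melatonin replicates 1 and 3 stand at 2.19 and 1.03 for the extracellular matrix list, and melatonin replicate 2 at -2.79 for the slow fibre list.

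The clock and antioxidant lists, both tied to melatonin, did not pass, and the list of melatonin receptors and metabolism had too few genes past the filter to be tested. The symbols of its receptors, MTNR1A and MTNR1B, were not found in the gene table. NQO2, a quinone reductase that binds melatonin, measured 2.35 ± 0.372 FPKM in controls and 2.52 ± 0.886 after melatonin, and its fitted change was -0.01 ± 0.23 and took the other sign in limma on FPKM. The circadian clock list of 21 genes had a median of -0.02, a mean of 0.03 and a downward test (limma camera adjusted p = 0.841). PER1 measured 12.8 ± 7.67 and 14.6 ± 5.86 FPKM, NR1D1 5.65 ± 3.04 and 6.24 ± 0.805, and ARNTL, which encodes the clock activator BMAL1, 1.498 ± 0.650 and 2.29 ± 0.419. NFIL3, a repressor on the output side of the clock, had the smallest p of the list (0.922 ± 0.242 and 2.80 ± 1.98 FPKM, 1.41 ± 0.44), followed by CRY1 (0.59). At an unadjusted p under 0.05 in edgeR, 3 members of the list were higher and 3 lower. Another fixed list, of the PER, CRY, NR1D and PAR bZIP arm of the clock, was lower in 8 of 12 genes. Its median was -0.20 (limma camera adjusted p = 0.169, and 0.0408 without control replicate 2). Antioxidant genes were lower in 20 of 30, with a median of -0.13 (limma camera adjusted p = 0.0997, and 0.0453 without control replicate 2). The superoxide dismutases SOD1 and SOD2 measured 12.3 ± 1.91 and 54.4 ± 11.6 FPKM in controls and 13.2 ± 3.82 and 52.0 ± 13.3 after melatonin, and catalase, CAT, 55.2 ± 23.1 and 60.9 ± 12.8. Peroxiredoxin PRDX2 (-0.30) and glutathione reductase GSR (-0.55) had the smallest p of that list.

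Growth and nerve pathways held isolated genes with small p. Growth hormone and IGF signalling did not pass (22 genes, median 0.14, limma camera adjusted p = 0.0817), with IGF1R (0.91) and IGFBP3 (0.85) leading. It passed without control replicate 4 (limma camera adjusted p = 0.0435), with quantile scaling (0.0359) and with library weights (0.0303). IGF1 was under the expression filter at 0.372 ± 0.0867 and 0.351 ± 0.198 FPKM. Myostatin and BMP signalling just missed the threshold (19 genes, median 0.25, limma camera adjusted p = 0.0517) and passed without control replicate 4 (0.0435), melatonin replicate 2 (0.0253) or melatonin replicate 4 (0.0326). The same list passed with median-of-ratios scaling (limma camera adjusted p = 0.0116), quantile scaling (0.0136), TMM-scaled log2 CPM (0.0227), no filter (0.0303), the replicate block (0.0339) and library weights (0.0436). MSTN, the brake on muscle growth, measured 3.77 ± 2.03 and 4.88 ± 1.36 FPKM (0.33 ± 0.37), and the smallest p of the list belonged to ID2 (1.02) and the activin receptor ACVR2A (0.48). The nerve-muscle junction and denervation list did not pass (10 genes, median -0.09, limma camera adjusted p = 0.257). In it CHRNE was the 1 gene to pass when adjusted over the list alone, and NCAM1 was higher (0.81). Immediate early genes did not pass (20 genes, median -0.12, limma camera adjusted p = 0.470), and adjusted over the list alone 2 went opposite ways, DUSP1 down and FOSL2 up (1.39 and 4.67 FPKM, 1.62). Calcium handling (27 genes, median -0.06, adjusted p = 0.622) and cytosolic ribosomal proteins (73 genes, median 0.00, adjusted p = 0.584) did not pass either. The ribosomal list did pass with quantile scaling (limma camera adjusted p = 0.00782) and without melatonin replicate 4 (0.0481). Both lists passed in the opposite direction without melatonin replicates 1 and 3 (adjusted p = 0.00849 and 0.0395).

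Of the 44 lists tested, 14 passed, 7 lower and 7 higher, and 30 did not. With an estimated correlation 0 passed (smallest adjusted p = 0.744), and by fry 0 passed. Among the others that did not pass were lipolysis (median 0.70, 6 of 6 genes higher, adjusted p = 0.0625), fatty acid genes (median -0.22, adjusted p = 0.0681), satellite cell markers (median -0.43, adjusted p = 0.0731) and the interferon response (median -0.04, adjusted p = 0.169). Myokines and secreted muscle factors (median 0.39, limma camera adjusted p = 0.0517) and cholesterol synthesis (median -0.18, 0.0681) also missed the threshold. With median-of-ratios scaling, among other settings, both passed (limma camera adjusted p = 0.0233 and 0.0432). Lipolysis passed without control replicate 3 (adjusted p = 0.0155) or melatonin replicate 4 (0.0101), and fatty acid genes without control replicate 2 (0.000601), control replicate 4 (0.0289) or melatonin replicate 3 (0.00741). With the replicate block, lipolysis, fatty acid genes (limma camera adjusted p = 0.0339 each) and satellite cell markers (0.0440) passed. Other settings in which lipolysis and fatty acid genes passed included median-of-ratios scaling (limma camera adjusted p = 0.0377 and 0.0432) and ranked camera (0.0438 and 0.0213). The interferon response passed as lower without melatonin replicate 2 (adjusted p = 0.00400) or 3 (0.00233), and in the opposite direction without melatonin replicate 4 (0.0190), whose list mean was -1.31 against -0.01 to 0.40 in the other treated libraries. Without melatonin replicates 1 and 3 together it passed as lower (adjusted p = 0.000585). In 6 of the 44 lists the median, the mean and the test differed in sign, and none of these passed. Across the 44 lists, 20 memberships passed in edgeR when adjusted over the list alone and 0 when adjusted over all genes. DESeq2 called some members over all genes, such as CHRNE and PDK4 (adjusted p = 0.00251 and 0.0323). Annotation terms deposited with the genes were tested too. Of 1586 GO and KEGG terms, 54 passed in limma camera, 20 higher and 34 lower. The smallest adjusted p belonged to the KEGG term oxidative phosphorylation (102 genes, median -0.33, adjusted p = 4.55e-15), followed by the GO term mitochondrial inner membrane (205 genes, median -0.27). The higher terms were led by collagen-containing extracellular matrix (80 genes, median 0.53, adjusted p = 8.45e-06). No term passed with an estimated correlation (0 of 1586, smallest adjusted p = 0.999), and leaving out melatonin replicate 1 brought the 54 to 16. The list count likewise went from 14 to 6 without melatonin replicate 1.

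Library makeup overlapped between the groups in all but 1 of the 4 measures. The number of genes at an FPKM of at least 1 was 9455 ± 351 in controls and 9801 ± 711 after melatonin (SD, n = 4, two-sided exact permutation p = 0.429). Total FPKM was 381564 ± 2131 and 367469 ± 8843, with no overlap (exact permutation p = 0.0286, the smallest that 70 assignments allow, adjusted p = 0.114). The 10 most abundant genes, led by the actin gene ACTA1 and by GAPDH at means of 62105 and 30344 FPKM, took 47.0 ± 3.40% and 44.1 ± 6.35% of the total (exact permutation p = 0.429), with 38.8 and 38.3% in melatonin replicates 1 and 3. The median log2 deviation of all genes was -0.04 ± 0.10 and 0.03 ± 0.18 (exact permutation p = 0.486).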

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

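The check for a library standing apart was chosen before its results were seen, and no pattern is weighed here. In 272 groups of 4 libraries (named genes, lists, myosin shares and library makeup, each in both groups), the gap from the highest or lowest library to the nearest other, divided by the range of the group, was above the Dixon limit in 16. Chance alone gives about 14, or 1 in 20, so the values below are given without an explanation.

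Fibre and fat measures had libraries apart. MYH7 was low in melatonin replicate 2, at 9.85 log2 CPM against 12.20 to 12.59 in the others (gap over range 0.857), as was the slow fibre list in the same library, at -2.79 against -0.33 to 0.13 (0.842). The MYH1 share was low in control replicate 4, at 21.2% against 39.8 to 41.6% (0.911). The adipocyte list was high in control replicate 3, at 2.03 against -0.77 to -0.59 (0.936), and so was the fat regulator PPARG, at 2.34 against 0.63 to 0.90 log2 CPM (0.844). Calcium handling genes were high in control replicate 2, at 0.25 against -0.10 to -0.07 (0.915), and proteasome genes in control replicate 4, at 0.29 against -0.11 to -0.08 (0.916).

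Individual genes, in log2 CPM, and a measure of library makeup gave the rest. RASGEF1B was low in control replicate 4, at 0.46 against 1.66 to 1.81 (gap over range 0.884). LIMD1 was low in melatonin replicate 2, at 3.05 against 3.47 to 3.49 (0.960). MYF5 was high in melatonin replicate 3, at 2.10 against 1.03 to 1.17 (0.864). ATF6 was low in control replicate 4, at 4.39 against 4.61 to 4.66 (0.833), and high in melatonin replicate 3, at 5.21 against 4.78 to 4.84 (0.871). MRPL24 was low in control replicate 4, at 5.54 against 5.78 to 5.81 (0.884). ARNTL was low in control replicate 1, at 0.97 against 2.44 to 2.71 (0.842). SOD2 was low in melatonin replicate 1, at 5.80 against 6.52 to 6.66 (0.846). The median log2 deviation of all genes was low in control replicate 2, at -0.19 against -0.00 to 0.01 (0.946). Control replicate 4 was the library apart in 5 groups and melatonin replicate 4 in 0.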

How the results depend on the processing

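Chosen after the results were seen were leaving out melatonin replicates 1 and 3 together, camera on TMM log2 CPM and the bias-adjusted quasi-likelihood test, and limma on FPKM became an alternative once counts were seen. Genes called stayed at 0 in every setting except DESeq2 (65) and leaving out melatonin replicate 4 (range 0 to 15 over the libraries left out). The 211 genes at an unadjusted p and 2-fold became 61 in limma on log2(FPKM + 1), 124 with a pseudocount of 0.1, 834 with no filter (more genes tested), 92 at a mean FPKM of 5 (fewer genes tested), 51 after quantile scaling (36 higher, 15 lower) and 95 without melatonin replicates 1 and 3 (49 higher, 46 lower). They ranged from 140 to 412 with a library left out. The cause was not tested where none is given.

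The 14 lists became 0 with an estimated correlation and 0 by fry, and ranged from 6 to 20 with a library left out. They became 19 with median-of-ratios, quantile or TMM log2 CPM scaling, and 17 with ranked camera. The 54 terms became 0 with an estimated correlation and 17 without melatonin replicates 1 and 3, and ranged from 16 to 76. Without both libraries the direction reversed for fast fibre (adjusted p = 0.000144), glycolysis (0.00099), matrix (0.569), calcium handling (0.00849) and cytosolic ribosomal genes (0.0395). With a single library left out, the interferon response ranged from an adjusted p of 0.00233 (without melatonin replicate 3) to 0.242 (without control replicate 4), also passed without melatonin replicate 2 (0.00400), and reversed without melatonin replicate 4 (0.0190). The cause was not tested. Robust hyperparameters were not run for lists, since camera has no such option. Of 1702 pairs of a named gene and a setting, 32 changed sign, in 9 of 83 genes, and 28 of the 83 passed in some setting, by DESeq2 or without melatonin replicate 4. Of the pairs of a list and a setting, 788 kept their direction and side of the threshold, 58 passed where the main test had not, 68 no longer passed and 6 reversed.

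The replicate numbers were not shown to pair the samples: same-number correlations were 0.18, 0.07, 0.17 and -0.03. Libraries numbered 1 and 3 correlated best with their own number. Control replicate 2 and melatonin replicate 4 were each other's best partners, as were control replicate 4 and melatonin replicate 2. The replicate block gave 0 genes called, 135 at an unadjusted p and 2-fold (95 higher, 40 lower), 19 lists and 60 terms. Myosin shares and library makeup passed in 0 of 44 pairs each, where an exact sign-flip test on the block cannot go below 0.125.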

Other observations

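Tests of fibroblasts, of a shared response, of a loss of fibre RNA and each test on the atrophy genes were chosen after the results were seen, and the tests of tendon tissue, of dilution and of length in the respiratory chain, and of other splits before. Beyond the named genes, the small lists gave values without a test. Of the melatonin receptor and metabolism list, 3 genes passed the filter, too few to test. CYP1A1, an enzyme that can hydroxylate melatonin, measured 1.53 FPKM in controls and 0.928 after melatonin, and it was chosen after its values were seen. A short gene model on chromosome X (22067693 to 22067767), ENSSSCG00000054645, measured 51.9 ± 60.0 FPKM in controls and 1.14 ± 1.09 after melatonin (log2 fold change -5.55 ± 1.503, edgeR adjusted p = 0.440) and was likewise chosen after its values were seen. Tendon regulators and matrix genes outside the fixed lists, chosen after their values were seen, included fibromodulin, FMOD, at 5.56 ± 1.06 FPKM in controls and 153 ± 210 after melatonin, and the tendon transcription factor MKX, at 0.0771 ± 0.0398 and 2.34 ± 3.45 FPKM. Of the 65 genes DESeq2 called, 50 of them higher, 27 had melatonin replicates 1 and 3 above all 6 other libraries. The share was 10.2% over all genes and 3.57% by chance. Genes called as higher have high treated libraries by selection, so neither share is a base rate for them.

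Tendon-like matrix genes were high in melatonin replicates 1 and 3. A response of that size shared by all treated piglets is argued against by 10 tendon and cartilage genes whose values had not been examined. In their mean, the higher of melatonin replicates 2 and 4 lay -0.18 from the highest control (control SD 0.29). It lay -1.20 from the lower of replicates 1 and 3. A smaller rise in replicate 2 stays open. In the 14 tendon genes picked for the pattern its mean was 0.72, above the highest control at 0.28. Replicate 4 had a mean of -1.03 there, but its median over the same genes was -0.07, inside the control medians of -0.12 to 0.27. More fibroblasts of the usual muscle kind stay open as a cause. Over melatonin replicates 1 and 3 against the other 6 libraries, the median log2 ratio of the fibroblast list was 0.93 (highest member SMOC2 at 2.23). It lay -3.65 (SE over genes 0.69) from that of 24 tendon genes. Of these, 14 were picked because they showed the pattern, so a gap was built in and cannot decide the question. Against the 10 unexamined genes alone (1.30) the gap was -0.38 (SE over genes 0.79). Tendon or fascia taken with the muscle in melatonin replicates 1 and 3 is a candidate explanation. Of the 10 unexamined genes, 60% had both libraries above all others (exact 95% interval 26.2 to 87.8%), against 10.2% of all genes. The interval takes the genes as independent, although all were read in the same libraries. Since both libraries belong to the treated group, a response of these animals alone to melatonin stays open and was not tested.

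Respiratory chain and TCA genes were lower after melatonin. A bias by transcript length or expression level stays open: complex I genes lay at -0.24 from their 20 nearest genes in length and expression, beyond the limit set against that bias, but with an SE between libraries of 0.16. Dilution of muscle RNA by other tissue in melatonin replicates 1 and 3 stays open too, because the complex I median without both libraries was -0.25, below the limit set against dilution, with a spread between libraries (SE 0.26) that includes 0. Without both libraries, complex I and complexes II to V still passed (limma camera adjusted p = 7.59e-05 each), as did mitochondrial ribosomal proteins (0.0017). These calls use the preset correlation and do not decide the question. In mean complex I level, melatonin replicates 2 and 4 lay at -0.22 and -0.21, inside the control range of -0.41 to 0.29. A loss of RNA shared by all fibre genes and a response to melatonin stay open too, since the fast fibre list lay 0.28 above complex I with an SE of 0.21 and the response was not separated from these.

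Atrophy genes were higher in melatonin replicates 1 to 3. A response shared by all treated piglets stays open: melatonin replicate 4 lay -0.016 from the highest control, inside the control range. Fasting or handling before sampling that differed between piglets may also contribute, as 10 glucocorticoid targets outside the atrophy list were 0.30 higher on average in those 3 libraries, but control replicates 1 and 2 reached 0.26 and 0.28. These cannot be told apart with 4 libraries per group.

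Chance was not excluded for the counts of genes at an unadjusted p, lists or terms. Over the 35 splits of the 8 libraries into groups of 4, 5 gave at least the 211 genes at an unadjusted p and 2-fold (highest other 284), 19 at least the 14 lists (highest other 24) and 12 at least the 54 terms (highest other 92). For the 0 genes called the count decides nothing, since 35 of 35 splits must give at least 0 (highest other 22). The split with 22 genes set control replicates 1 to 3 and melatonin replicate 4 against the rest. It was singled out after the counts were seen, and whether it reflects a structure of the samples was not tested.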
